A study of Mus musculus with 6 samples.

How the data were processed

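Gene expression was measured in KSL cells (c-Kit positive, Sca-1 positive, negative for lineage markers) sorted from mouse fetal liver or adult bone marrow. KSL cells are the fraction of blood-forming tissue that holds the hematopoietic stem cells (HSCs). The 6 samples fall into 4 groups by tissue and genotype. In the knockout (KO), both alleles of the gene for TIF1b, listed in the reference as Trim28, are floxed. The fetal liver samples carry Tie2-Cre and the bone marrow samples CreERT, and there is 1 WT and 1 KO sample from fetal liver and 2 WT and 2 KO samples from bone marrow. The genotype labels of bone marrow replicate 2 read Tif2b in place of Tif1b and were taken as the same gene. Nothing in the labels says that samples of a group came from separate animals, so p-values may measure only the spread between these samples, which could be technical.

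Per the labels' protocols, 10 ng of total RNA was amplified, labelled with Cy3 and hybridised to Agilent 1-colour arrays. The deposited scanner files hold the intensity of each of 62976 spots. They were made with Agilent Feature Extraction 10.7.1.1, per the submitters' processing notes, and gProcessedSignal is the background-corrected signal, per the file headers. A table of values deposited by the authors holds a linear ratio per probe and sample. Its scale was found by setting each column against the same sample's scanner intensities. For 5 of the 6 samples the column was the scanner signal divided by a constant, with 99.895% to 99.960% of the probes with a ratio of at least 0.1 within 1% of it. The constant lay close to the array's 75th percentile. The ratio therefore has the same direction as the signal and no centring of genes was seen. The column medians were 0.0705 for fetal liver WT, 0.0709 for fetal liver KO, 0.057 and 0.056 for bone marrow WT and KO replicate 1, and 0.063 and 0.064 for bone marrow WT and KO replicate 2. The exception was the array labelled bone marrow WT replicate 1, whose table column matched its scanner file within 1% for 1.54% of those probes.

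The main values were log2(gProcessedSignal) minus each array's 75th percentile. Control spots and outlier-flagged spots were left out and the log2 values of repeated spots of a probe were averaged. Probes were given gene symbols through their RefSeq accessions in the reference. This named 26762 of 55681 probes, for 20284 genes, and each gene is represented by its brightest probe. Genes were tested where the probe was well above background (Agilent's flag) on all arrays of at least 1 group. For the value table's column of the array labelled bone marrow WT replicate 1 the flags of the scanner file could not be used, and a level of -3.7 on the log2 scale replaced them. It was chosen on the bone marrow KO array of the same slide, where it matches 99.1% of the flags. No genome was used, so no coordinates are given.

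Tests were run with limma 3.58.1 in R 4.3.3 with the data.table package (version 1.17.8), using lmFit and eBayes, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05. Bone marrow KO was compared with WT over the 4 bone marrow arrays. The genotype effect over both tissues and the tissue effect came from 1 model of tissue plus genotype over all 6 arrays. The interaction contrast assumes that the lone fetal liver arrays vary like the bone marrow arrays. Fetal liver KO and WT are 1 array each, so only differences are given. A total of 36 gene lists of cell types, pathways and gene families was fixed before the data were examined. A list with at least 5 measured genes was tested in bone marrow with camera at its preset correlation of 0.01 and again with an estimated correlation. In fetal liver a list's median difference was ranked among 10000 random lists of the same size, matched on mean expression in 10 bins. Correlations are across genes, which are not independent replicates.

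Each slide holds 1 WT and 1 KO array of 1 tissue and was scanned on its own, so the 3 slides are also the 3 replicate pairs. Bone marrow gene counts and list tests are given with the slide as a block, list medians and some single genes per pair, and the tissue result with the slide as a random block. Calls of single bone marrow genes and of list members come from the fit without the block. A probe well above background on no array of the dimmer group gives only a bound. The fold is then written as at least N-fold, from the brighter group's mean over the dimmer group's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background. Such a bound holds for the scanner's own background correction only. No bound is given where another probe of the gene was above background in the dimmer group. The number of arrays limits the precision throughout, and signal over background differed between them, as the report gives per array.

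The genes named were chosen by a rule fixed together with the lists. It takes Trim28 and the HP1 genes Cbx1, Cbx3 and Cbx5, and in bone marrow the 12 genes that changed most in each direction with no overlap between groups. Places left were filled by genes ranked on the gap between the groups, as values. It also takes the 10 highest and 10 lowest differences in fetal liver, the 10 highest and 10 lowest over both tissues, the 10 largest tissue differences in each direction, and up to 4 members per list. Clone and predicted-gene names were counted but not named, and Y-linked genes and Xist were left out. Kit and Ly6a, which encode the sorting markers c-Kit and Sca-1, were added after their values were seen.

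The design set the scanner files as the source of values and the value table as an alternative. The mismatch of the array labelled bone marrow WT replicate 1 was found after the files were read. The scanner files, the value table, and scanner files with the table's column for that array were then each fitted with and without the slide block, and their numbers of passing genes were seen, before the table was given space beside the scanner files. That choice rests on the mismatch of the signals and on the level of Kit, not on Trim28, which is the knocked-out gene. Every bone marrow result therefore stands for the scanner files first and for the value table second, and the value table's own alternatives were added after its results were seen.

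The alternatives were quantile or median scaling, no filter or a filter on all arrays, the mean over a gene's probes, outlier spots kept, normexp background correction with an offset of 50 on the median signals, an intensity trend in eBayes, a fold limit of 2, every probe on its own, fry, the blocks, and leaving out each bone marrow array. In simulated data of 13011 genes, with each gene's spread taken from the difference of the bone marrow KO arrays, the bone marrow fit, at 2 arrays against 2, recovered 0%, 24%, 48% and 64% of genes changed 2-fold, 4-fold, 8-fold and 16-fold, with 4 false calls. The fit over both tissues, at 3 against 3, recovered 26%, 48%, 82% and 84%, with 2 false calls. All simulated arrays took the spread of the KO arrays, which correlated at r = 0.974 in the scanner files, against 0.889 for the bone marrow WT arrays. The scanner files can therefore recover fewer genes than these shares, and 0 passing genes there does not show that large changes are absent. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3.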

Results

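TIF1b, encoded by Trim28, is a corepressor that binds HP1 proteins and takes part in the silencing of chromatin. The arrays address how its loss alters gene expression in KSL cells, the stem cell fraction, of fetal liver and of adult bone marrow. The 6 arrays were 1 WT and 1 KO array from fetal liver, and 2 WT and 2 KO arrays from bone marrow. In fetal liver, 24385 (WT) and 24588 (KO) probes were well above background, at a 75th percentile signal of 219 and 211. In bone marrow replicate 1 these were 27581 probes for WT and 25812 for KO, at signals of 281 and 325. Bone marrow replicate 2 was brighter, with 31423 (WT) and 31275 (KO) probes above background and signals of 737 and 743. Saturation affected 1 probe on the bone marrow WT replicate 2 array and none on the others. Values below are log2 signals relative to the array's 75th percentile, and differences are KO minus WT unless stated otherwise.

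Trim28 was lower on every KO array than on every WT array. Its level was 5.97 in fetal liver WT and 1.68 in fetal liver KO. In bone marrow it was 5.55 in WT replicate 2, 1.28 in KO replicate 1 and 0.75 in KO replicate 2. The array labelled bone marrow WT replicate 1 had a Trim28 level of 2.45 in its scanner file and of 5.18 in the authors' value table. Whether the single Trim28 probe lies in the deleted part of the gene is unknown, so it checks the genotype labels only if it does. In the value table Trim28 fell by 4.34 ± 0.31 (SE, n = 2 arrays per genotype, limma adjusted p = 0.0161), a 20.3-fold difference. In the scanner files the difference was -2.98 ± 1.07 and did not pass (adjusted p = 1.00). In fetal liver it was -4.30, or 19.6-fold, from 1 array each. The HP1 genes Cbx1, Cbx3 and Cbx5, whose proteins bind TIF1b, differed by 0.19, 0.28 and 0.41 in the bone marrow scanner files and by 0.08, 0.01 and -0.01 in the table, and none passed.

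The scanner file of the array labelled bone marrow WT replicate 1 differed from its table column in cell type genes as well. Kit, which encodes the sorting marker c-Kit, was at 1.30 in the scanner file and 4.16 in the table, against 4.17 to 4.5 on the other 5 arrays. Ly6a, the gene of the other sorting marker Sca-1, was at 4.48 and 3.36. It was at 4.75 in bone marrow WT replicate 2, and at 3.60 and 6.04 in KO replicates 1 and 2. The scanner value lay within this bone marrow range and the table value below it. In fetal liver Ly6a was at 0.31 in WT and 0.77 in KO. Over all the other 5 arrays both the scanner and the table value lay within the range. Ly6a therefore did not favour the table column as Kit did. B lymphoid genes had a median 5.77 higher in the scanner file than in the table and T, NK and innate lymphoid genes 3.42 higher. The 4 measured haemoglobin genes had a median 8.23 higher, with the lowest of them 0.87 higher. HSC-associated genes were 2.55 log2 units lower (median -2.55) and megakaryocyte genes 4.42 lower (-4.42). Over 21580 probes above background on all 6 arrays, 4415 were over 2-fold apart. Across genes the WT arrays of bone marrow correlated at r = 0.889 with the scanner file and 0.983 with the table column, and the KO arrays at 0.974. A description line of the same sample names a knockdown of Hp1a in c-Kit positive, lineage-negative cells, and that of bone marrow KO replicate 1 a knockdown of Hp1g, while their other labels give KSL WT and KO. The array is therefore called by its label throughout, and each bone marrow direction from the scanner files draws on it.

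**Figure D1:**
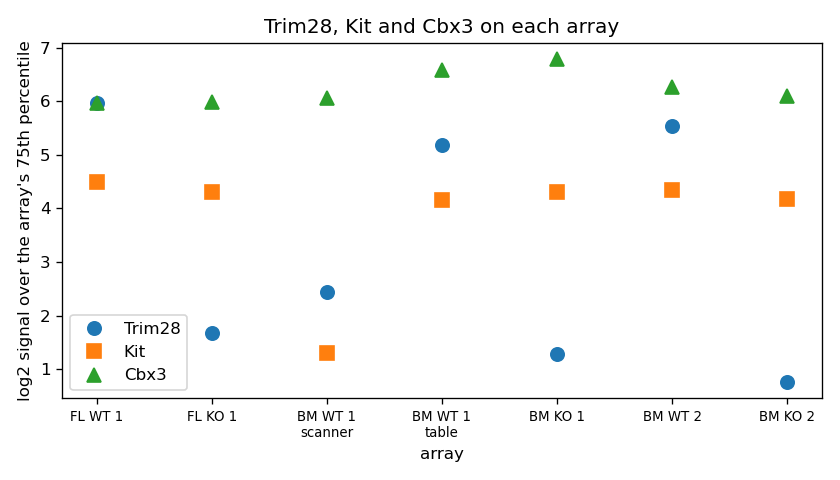
Log2 signal over the array's 75th percentile (vertical axis) of Trim28, Kit and Cbx3 on each array, with 1 point per gene and array; the array labelled bone marrow WT replicate 1 is drawn from its scanner file and from the value table. On that array Trim28 was at 2.45 and 5.18 and Kit at 1.30 and 4.16, while Kit lay between 4.17 and 4.5 on the other 5 arrays.

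In bone marrow, genes of stem cells, megakaryocytes, erythroid cells and mast cells lay higher as groups in KO than in WT KSL cells, and genes of neutrophils lay lower, in both sources of values. Genes of monocytes lay lower in the scanner files, and in the table by an amount that depended on the scaling. The HSC-associated list, which holds the stem cell surface marker Slamf1 and the transcription factor gene Mllt3, had a median difference of 1.94 over 42 genes in the scanner files (camera adjusted p = 6.15e-10) and 0.62 over 41 genes in the value table (9.20e-08). The megakaryocyte list, with the platelet glycoprotein genes Gp5 and Gp9, had medians of 2.70 and 0.73 (adjusted p = 1.06e-07 and 7.53e-07). The neutrophil and granulocyte list had medians of -2.81 and -1.77 (8.09e-12 and 4.99e-13). With an estimated correlation the calls were lost for each of these, with adjusted p = 0.835 in the scanner files for all 3 lists, and 0.4997, 0.4997 and 0.540 in the table.

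Of the 41 HSC-associated genes in the value table, 35 were higher in KO. The surface glycoprotein gene Thy1 rose by 2.75 ± 0.34 (limma adjusted p = 0.0426) and no other member passed over all genes, while 3 members passed adjusted over the list alone. Slamf1 differed by 1.72 ± 0.32 and Mllt3 by 1.52 ± 0.26 without passing. In the megakaryocyte list 20 of 23 genes were higher, 0 passed over all genes and 9 passed adjusted over the list alone, with Gp9 at 1.79 ± 0.25 and Gp5 at 1.72 ± 0.31. The HSC-associated and megakaryocyte lists share 4 genes. The median of the HSC-associated genes was 0.49 in replicate pair 1 and 0.54 in pair 2 of the table, and 3.10 and 0.55 in the scanner files. For megakaryocyte genes it was 0.72 and 0.77 in the table, and 4.81 and 0.73 in the scanner files.

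Among neutrophil genes, the collagenase gene Mmp8 fell at least 5.37-fold in the value table, neutrophil elastase (Elane) fell by 4.27 ± 0.51, the calcium-binding protein gene S100a9 by 3.21 ± 0.27 and the cathelicidin gene Camp by 2.74 ± 0.25 (limma adjusted p = 0.044, 0.0391, 0.019 and 0.0208). These were the 4 of 24 members that passed over all genes, and 15 passed adjusted over the list alone. The list's median was -2.40 and -1.45 in pairs 1 and 2 of the scanner files, and -2.32 and -1.55 in the table. In the monocyte, macrophage and dendritic list, whose medians were -1.87 and -0.20 (camera adjusted p = 5.31e-08 and 0.0123; 0.835 and 0.585 with an estimated correlation), Mpeg1, Irf8 and Csf1r fell in the table by 4.76 ± 0.35, 4.14 ± 0.45 and 3.00 ± 0.40. Mpeg1 encodes a pore-forming protein of macrophages, Irf8 a transcription factor of monocytes and dendritic cells, and Csf1r the macrophage colony-stimulating factor receptor. Of this list 3 of 23 genes passed over all genes and 6 adjusted over the list alone. In pair 2 its median was 0.07 in the scanner files and -0.01 in the table, so the shift of the median lay in pair 1. The members went both ways, with 11 of 23 higher in KO in the table. Mpeg1 (-5.03 and -4.49) and Irf8 (-4.57 and -3.71) fell there in pairs 1 and 2 alike. With quantile scaling the monocyte median of the table was -0.0055.

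Erythroid genes had a median of 0.58 in the scanner files and 1.23 in the table (camera adjusted p = 0.0320 and 3.02e-08; 0.835 and 0.614 with an estimated correlation). The alpha-globin genes Hba-a1 and Hba-a2 differed by 5.60 ± 1.30 and 5.50 ± 1.31 in the table without passing, and 8 of 22 erythroid genes passed adjusted over the list alone against 0 over all genes. The Hba-a1 difference in the scanner files was -2.81 in pair 1 and 3.51 in pair 2. Mast cell and basophil genes had medians of 1.85 and 0.97 (adjusted p = 2.55e-05 and 0.000466; 0.835 and 0.590 with an estimated correlation), with the IgE receptor gene Fcer1a at 2.92 ± 0.43 and the carboxypeptidase gene Cpa3 at 2.69 ± 0.60 in the table. Here 0 of 18 genes passed over all genes and 3 adjusted over the list alone. With the slide as a block the adjusted p of these 6 lists was at most 0.0112 in the scanner files and 0.0390 in the table.

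Lymphoid genes shifted in the scanner files alone, and B lymphoid genes went opposite ways in the replicate pairs. B lymphoid genes had a median of -2.96 over 20 genes (camera adjusted p = 1.86e-09), made of -7.02 in the pair with the array labelled bone marrow WT replicate 1 and 1.15 in pair 2. In the value table the median was 0.10 over 13 genes while camera's direction was down (adjusted p = 0.0874). T, NK and innate lymphoid genes had a median of -2.00 (adjusted p = 2.34e-06) in the scanner files, from -3.39 and -0.22 in pairs 1 and 2, and -0.23 (0.755) in the table. Also in the scanner files alone, chemokine and inflammatory genes shifted down (-0.35, adjusted p = 0.0212), and epithelial genes (0.28, 0.0384) and the 313 zinc finger genes named Zfp (0.18, 0.0126) shifted up. In pairs 1 and 2 the medians were -0.93 and 0.09 for chemokine genes, 0.14 and 0.28 for epithelial genes, and 0.37 and 0.0021 for Zfp genes, so the chemokine and Zfp shifts lay in the pair with the array labelled bone marrow WT replicate 1. With an estimated correlation the adjusted p was 0.835 for these lists and 0.929 for the Zfp genes.

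In the value table alone, ribosome biogenesis genes shifted down, with a median of -0.50 and 1 of 32 genes higher in KO (camera adjusted p = 2.20e-06, and 0.791 with an estimated correlation). Their scanner median was 0.17, from 1.03 in pair 1 and -0.72 in pair 2. Hepatocyte genes shifted down in the table (-0.92 over 9 genes, adjusted p = 0.0359), where alpha-fetoprotein (Afp) fell by 2.52 ± 0.31. The hepatocyte median was -1.14 in pair 1 and 0.10 in pair 2, so that shift lay in pair 1. Stromal genes shifted up (0.34, adjusted p = 0.00578), where Thy1 and the receptor gene Pdgfrb, at 2.32 ± 0.28, rose. HSC adhesion and niche genes also shifted up (0.14, adjusted p = 0.0342), and with an estimated correlation the adjusted p was 0.585 for these 3 lists. In all, 11 of 35 lists passed in the scanner files (6 up, 5 down) and 10 in the table (6 up, 4 down), 13 and 12 with the slide as a block, and 0 in either with an estimated correlation or with fry. The lists added by the block were imprinted (adjusted p = 0.0186) and muscle genes (0.0267) in the scanner files, and interferon-stimulated (0.0390) and oxidative phosphorylation genes (0.0194) in the table. The median and camera's direction differed in sign for the interferon, mitosis and neural lists in the scanner files, and for the germline, fetal HSC, B lymphoid and immediate early lists in the table, none of which passed.

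**Figure D2:**
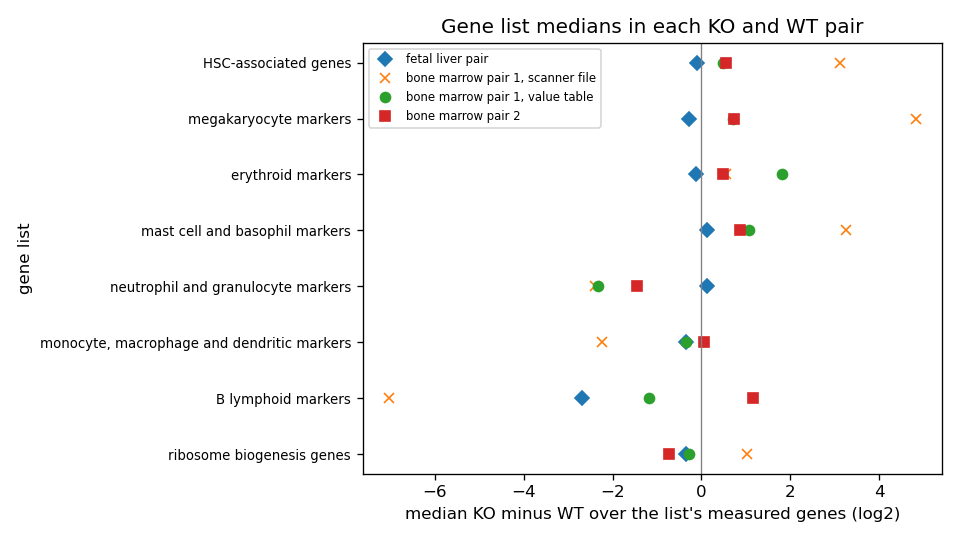
Median KO minus WT log2 difference (horizontal axis) of 8 gene lists (vertical axis), with 1 point for each of the fetal liver pair, bone marrow pair 1 from the scanner file and from the value table of its WT array, and bone marrow pair 2. HSC-associated genes lay at 3.10 and 0.49 in bone marrow pair 1 and 0.55 in pair 2, and B lymphoid genes at -7.02 and -1.19 in pair 1, 1.15 in pair 2 and -2.70 in fetal liver.

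Cyp2b10, Ak7, Ppp1r3g, Ifi44l, Gbp2b and Upk1b were among the genes furthest apart between bone marrow KO and WT in the value table. In the value table the cytochrome P450 gene Cyp2b10 rose at least 135-fold, the adenylate kinase gene Ak7 at least 70.0-fold, and Ppp1r3g, a glycogen-targeting subunit of protein phosphatase, at least 39.97-fold (limma adjusted p = 0.00774, 0.00517 and 0.00965). The interferon-inducible genes Ifi44l and Gbp2b rose at least 26.3-fold and 25.4-fold, and the uroplakin gene Upk1b at least 23.6-fold. The list of interferon-stimulated genes did not pass in either source (camera adjusted p = 0.707 in the scanner files and 0.104 in the table). With the slide as a block it passed in the table (adjusted p = 0.0390), and not with an estimated correlation (adjusted p = 0.932). Lrrn3, Scin, Skint3, Spock2 and the epithelial adhesion gene Epcam rose by 5.41 to 5.95, Skint3, Spock2 and Epcam being above background on 1 of the 2 WT arrays, and Spata21 rose as well, with no bound because another of its probes was above background in WT. In the scanner files the pair with the array labelled bone marrow WT replicate 1 went the other way for Upk1b (-2.10), Skint3 (-0.60) and Ifi44l (-0.56). Atp8b5 fell at least 32.4-fold, Zfp874a 26.6-fold, the lipopolysaccharide-degrading enzyme gene Aoah 12.8-fold, Celsr3 and Kcng1 11.4-fold, and Tmem178 6.84-fold. Ly86, which encodes a partner of a Toll-like receptor homologue, fell by 5.77 ± 0.63, and Apoc1, Unc5a and Gria3, each above background on 1 of the 2 KO arrays, fell by 4.86 ± 0.34, 4.81 ± 0.28 and 4.72 ± 0.39. The scanner difference of pair 1 was above 0 for Unc5a (1.16), Apoc1 (0.45) and Atp8b5 (0.19), which draws on the same array.

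Other list members that passed in the table were Cdkn2a, a locus of cell cycle inhibitors, which rose by 3.96 ± 0.42 (1 of 2 WT arrays above background), the chromatin organiser gene Satb1, which fell by 3.94 ± 0.30, and the natural killer receptor gene Klrd1, which fell at least 2.89-fold. Perp and Dsp, genes of desmosomes, rose by 3.43 ± 0.41 and 2.90 ± 0.25 (Dsp above background on 1 of 2 WT arrays), and the calponin gene Cnn3 fell by 3.22 ± 0.27. Hoxc9 rose at least 2.38-fold, Zfp963 rose by 2.06 ± 0.26 (1 of 2 WT arrays above background), Zfp456 fell at least 5.11-fold and the acute-phase gene Saa3 at least 2.502-fold.

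In the scanner files 0 of 13011 genes passed in limma, with 548 at an unadjusted p under 0.05. Values there were furthest apart, by the gap between the groups, for Cyp2b10 (at least 166-fold higher in KO, adjusted p = 0.1001), Ppp1r3g (at least 49.3-fold, 0.282), Sema4f, Ank3, Elovl2, Ror2, Fbln7, Fbp2, Gpr182, St6galnac5, Hddc3 and Ano1 on the higher side. On the lower side these were Ly86, Mpeg1, Mefv, Tmem178, Aoah, Gria3, Irf8, Mmp8, Pram1, Tctex1d1, Rab7b and Satb1. With normexp background correction the differences were smaller, at 5.22 for Cyp2b10 and 3.66 for Ppp1r3g. Of 12785 genes in the value table, 113 passed, 61 higher and 52 lower, with 1413 at an unadjusted p under 0.05. Of these 113 genes 99 were tested in the scanner files, where 95 had the same direction and 71 an unadjusted p under 0.05, in fits that share 3 of their 4 arrays. With the slide as a block 0 genes passed in the scanner files (699 at an unadjusted p under 0.05) and 982 in the table (505 higher, 477 lower). Without the array labelled bone marrow WT replicate 1 the scanner files gave 258 genes, without bone marrow WT replicate 2 they gave 2222, and without either KO array 0. Each of these fits leaves 1 array in a group, so the spread comes from the 2 arrays of the other group alone. By the same kind of fit the table gave 335 and 651 genes without WT replicate 1 and 2, and 571 and 448 without KO replicate 1 and 2. It gave 11 genes with no filter and 27 with the filter on all 4 arrays.

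In fetal liver, B lymphoid and hepatocyte genes lay lower on the KO array than on the WT array, and glycolysis, hypoxia and globin genes lay higher. There is 1 array per genotype, so no test was made. B lymphoid genes had a median difference of -2.70, and 11 of 16 were at least 2-fold lower. Vpreb3, part of the surrogate light chain family, was at least 48.1-fold lower, the transcriptional coactivator gene Pou2af1 7.73-fold and the recombinase gene Rag1 7.25-fold. Hepatocyte genes had a median of -1.26, with 10 of 18 at least 2-fold lower, Afp at -2.76 and the fibrinogen chain gene Fgb at least 2.51-fold lower. Glycolysis and hypoxia genes had a median of 0.55, and 8 of 31 were at least 2-fold higher, among them the mitophagy gene Bnip3 at 2.35, the glucose transporter gene Slc2a3 at 1.74 and the oxygen-sensing hydroxylase gene Egln3 at 1.61.

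Of 6 globin genes on the fetal liver arrays 5 were at least 2-fold higher in KO (median 1.58), led by the embryonic genes Hba-x at 2.92 and Hbb-bh1 at 1.82. Interferon-stimulated genes had a median of 0.31, with Oasl1 at 1.74 and Oas2 at 1.37. Stromal genes had a median of 0.44, with the collagen gene Col1a1 at 2.25, and epithelial genes one of 0.43, with Epcam at least 17.7-fold higher and Perp at 2.14. Chemokine genes had a median of 0.30, apoptosis genes 0.13, quiescence genes 0.13 and HSC adhesion genes 0.09. Neutrophil genes had a median of 0.13 with members on both sides, 5 at least 2-fold higher and 6 lower, such as lactoferrin (Ltf) at 3.40 and Elane at -2.05. Monocyte genes had a median of -0.35, megakaryocyte genes -0.29, ribosome biogenesis genes -0.35, oxidative phosphorylation genes -0.25 and mitosis genes -0.21. These 17 lists lay outside the central 95% of 10000 random lists of these arrays, and HSC-associated genes (-0.11, percentile 23.6) lay inside. The random lists do not keep genes of a cell type together, so lists of genes that vary together leave this range more easily. A place outside it describes these arrays and is not a test.

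Among single genes of fetal liver, Nccrp1 was 177-fold higher in KO, and the carbonyl reductase gene Cbr3 at least 99.98-fold, Sycn 81.4-fold, the ion transport regulator gene Fxyd4 64.8-fold, Ppp1r3g 49.6-fold, Upk1b 39.96-fold, Cyp2b10 15.8-fold and the fructose bisphosphatase gene Fbp2 13.7-fold. The cytochrome gene Cyp2a4 was also among the highest, with no bound because another of its probes was above background in WT. Apolipoprotein E (Apoe) was 36.7-fold lower, the transcription factor gene Dach1 at least 25.2-fold, the interferon-inducible gene Ifi202b 18.6-fold, and the mineralocorticoid receptor gene Nr3c2 11.4-fold. Cdk5r2, Fcamr, Tac1 and Olfr1129 were at least 7.36-fold to 9.35-fold lower. In bone marrow Ifi202b went the other way in the value table, where it rose at least 5.95-fold (limma adjusted p = 0.0177). Its difference in the scanner files was 0.18 ± 3.51, from -5.48 in the pair with the array labelled bone marrow WT replicate 1 and 5.84 in pair 2. Of 12701 genes, 677 were at least 2-fold higher in fetal liver KO and 561 lower, and the median difference was -0.07.

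Over both tissues, with 3 KO and 3 WT arrays, Ppp1r3g, Cyp2b10, Upk1b, Epcam, Spata21, Tmem150c, Gpr182, Eva1a, Rab40b and Trim9 rose in KO in the value table, and Trim28, Hk3, Mdga1 and Satb1 fell. Ppp1r3g was at least 39.97-fold higher in bone marrow and 49.6-fold in fetal liver (limma adjusted p over both tissues 0.0138), and Upk1b at least 23.6-fold and 39.96-fold (0.00996). Gpr182 was at least 4.58-fold and 3.77-fold higher (0.0176). The hexokinase gene Hk3 fell (-3.95 ± 0.25, adjusted p = 0.0176), as did Satb1 (-3.61 ± 0.29, 0.0273), Mdga1 (-3.91 ± 0.28, 0.0253) and Trim28 (-4.33 ± 0.22, 0.0138). Ak7, Fbp2, Nccrp1, Klrd1, Dach1, Apoe, Ear2, Gria3 and Eps8l1 lay apart in both tissues in the table without passing. Some of these directions were absent or turned in the bone marrow scanner files, where Nccrp1 differed by -0.03 ± 2.72, Dach1 by 0.85 ± 2.74 and Mdga1 by -0.31 ± 2.69. Pair 1, with the array labelled bone marrow WT replicate 1, stood there at -3.38, 4.47 and 3.73, and at -1.45 for Tmem150c. By the gap in the scanner files Ror2, Cap2 and Perp were also among the higher genes, and Plekhh1, Elane, Il2rb, Apba1, Vpreb1, Wfdc21 and P2ry6 among the lower.

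In the scanner files 0 of 13661 genes passed limma's test over both tissues, with 466 at an unadjusted p under 0.05, and with the slide as a block 0 passed (479). Of 13501 genes in the table, 23 passed, 18 higher and 5 lower, with 1399 at an unadjusted p under 0.05, and 0 with the slide as a block (2168). Without any 1 of the bone marrow arrays the table's count was 0, except without the array labelled bone marrow WT replicate 1, where it was 1. That array's removal also gave 1 gene in the scanner files, and quantile scaling 2.

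Across genes the KO differences of fetal liver and bone marrow had r = 0.0724 (rho = -0.0785) in the scanner files and r = 0.345 (rho = 0.289) in the table, over 12050 and 11986 genes. Genes at least 2-fold higher in both tissues numbered 126 in the scanner files, against 31.4 for independent lists, and 157 against 16.002 in the table. Genes lower in both were 92 against 19.04 and 103 against 13.3, and 153 and 65 genes went opposite ways, against 49.0 and 29.6, so opposite pairs were also above the value for independent lists. The scanner r was 0.295 without the array labelled bone marrow WT replicate 1 and -0.0456 without bone marrow WT replicate 2. In the test of the difference between tissues, the interaction, 0 genes passed in limma in either source, with 351 and 953 at an unadjusted p under 0.05. The scanner files gave 200 genes without the array labelled bone marrow WT replicate 1 and 1390 without bone marrow WT replicate 2. The table gave 154 to 273 without 1 array (154 and 212 without WT replicate 1 and 2, 273 and 206 without KO replicate 1 and 2) and 89 with quantile scaling.

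Between tissues, Lin28b, Igf2bp1, Igf2bp3 and the embryonic globin gene Hbb-y were among the genes furthest lower in bone marrow than in fetal liver KSL cells, in both sources of values. Lin28b, an RNA-binding regulator of the fetal stem cell programme, was at least 365-fold lower in the scanner files and at least 329-fold in the table (limma adjusted p = 0.00420 and 0.000690). Igf2bp1 and Igf2bp3, which encode RNA-binding proteins, were at least 154-fold and 82.9-fold lower in the scanner files. Hbb-y, above background on 1 of 4 bone marrow arrays, was lower by 10.34 log2 units (-10.34 ± 0.24, adjusted p = 0.000997). The eosinophil granule genes Prg3 (-7.51 ± 0.97), Ear1, Ear2, Ear6 and Rnase2a were lower in the scanner files (adjusted p = 0.0187 to 0.0363; Prg3, Ear1 and Rnase2a above background on 3 of 4 bone marrow arrays), and Olr1 at least 57.8-fold. The stefin genes Stfa1, Stfa3, Stfa2l1, Cstdc4 and Cstdc5 were among the lowest in the table, each above background on 3 of 4 bone marrow arrays, and with the slide as a random block Stfa1 and Cstdc5 did not pass (adjusted p = 0.0723 and 0.0663).

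Dntt, the template-independent DNA polymerase of lymphoid precursors, was at least 628-fold higher in bone marrow in the scanner files and at least 438-fold in the table (limma adjusted p = 0.0341 and 0.00279). The estrogen receptor gene Esr1 and Cngb1 were higher in both sources (adjusted p = 0.00420 and 0.0364 in the scanner files), with no bound because another probe of each was above background in fetal liver. In the scanner files Nlrc5, a regulator of class I histocompatibility genes, was at least 56.6-fold higher, the interferon-inducible gene Ifi44 38.1-fold, and H2-Q8 differed by 6.24 ± 0.36, with Gstt1, Phf11d, Clec10a (above background on 1 of 2 fetal liver arrays) and Tgtp2 following. In the table the joining chain gene Jchain, the mast cell genes Fcer1a and Mcpt4, and Aldh1a1, Clca3a1, Clca3a2 and Npdc1 were among the highest. Jchain, Fcer1a and Aldh1a1 were above background on 1 of 2 fetal liver arrays, and Fcer1a did not pass with the slide as a random block (adjusted p = 0.0670).

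Of 13661 genes in the scanner files 119 were higher and 168 lower in bone marrow, and of 13501 in the table, 1203 and 1885. The median gene lay at -0.30 (bone marrow minus fetal liver) in the scanner files with the 75th percentile, at -0.06 with quantile and at -0.11 with median scaling, and at -0.26, -0.04 and -0.01 in the table, and the differences above are to be read against it. With quantile scaling 186 were higher and 167 lower in the scanner files, and 176 and 148 with median scaling, and in the table these were 1575 and 1350, and 1399 and 846. With the slide as a random block the counts were 335 (139 higher, 196 lower) and 835 (373 higher, 462 lower). The estimated correlation within a slide was -0.0347 in the scanner files and 0.449 in the table. In the scanner files the block therefore did not allow for a shift shared by a slide's arrays. The scanner count was 1817 without the array labelled bone marrow WT replicate 1, 69 without bone marrow WT replicate 2 and 1 without either KO array. The table's was 1889 and 1223 without WT replicate 1 and 2, and 1852 without KO replicate 2. Tissue, age and Cre line change together here and cannot be told apart.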

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

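Of the tests below, those of the HSC-associated and neutrophil lists in pair 2 were written before their results were seen. The tests of scaling, exchange and B lymphoid RNA, and the regroupings of arrays, were chosen after the results were seen. Megakaryocyte genes had a median KO minus WT difference of -0.287 in fetal liver, while both bone marrow pairs lay above 0. Neutrophil genes had one of 0.129 in fetal liver, while both bone marrow pairs lay below 0. Both were listed because the list medians of the tissues had opposite signs, and the difference between tissues was not tested for either list. The neutrophil genes of fetal liver lay on both sides, 5 at least 2-fold higher and 6 lower.

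Trim28 stood at 5.18 in the table column of the array labelled bone marrow WT replicate 1, and was listed as a signal in data that the scanner files do not hold. Another 7233 probes without a gene symbol were well above background on all 6 arrays. Of 10600 probes without a symbol tested one by one in the bone marrow scanner files, 0 passed in limma, with 337 at an unadjusted p under 0.05.

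The scanner file and the table column of the array labelled bone marrow WT replicate 1 hold different measurements. Another scaling of the same hybridisation would leave the order of probes in place, but the Spearman correlation was 0.913, against over 0.998 for the other arrays. An exchange with another array of the series is also excluded, since at most 1.69% of probes lay within 1% of any other column. B lymphoid RNA may be present in the scanner file's sample, where B lymphoid genes were 5.77 higher, although the lineage-negative gate should remove such cells. T, NK and innate lymphoid genes were also higher, with a lower quartile of 1.74, which argues against B lymphoid RNA as the whole cause. It does not exclude it, since this test was added after the list's median was known. The list also shares 1 gene with the B lymphoid list. The haemoglobin genes met neither condition set for them. B lymphoid RNA as the whole cause required each to be under 1 higher, and the opposite required each to be above 1. The lowest of 4 was 0.87 higher and their median 8.23 higher. That median also argues against B lymphoid RNA as the whole cause, but this test too was added after it was known. A sample from another experiment, as a description line of that array reads, remains untested. That line names c-Kit positive, lineage-negative cells. Kit at 1.30 in the scanner file, against 4.16 in the table column, and the higher B lymphoid genes go against such a sort. Cbx5, the gene of Hp1a, was at 1.03 in the scanner file and 1.86 in the table column. The other bone marrow arrays had 1.58 to 2.20. The description line of bone marrow KO replicate 1 names Hp1g, whose gene Cbx3 was at 6.78 there, its highest value on any array. Single genes on single arrays do not decide this for either array.

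Could the array labelled bone marrow WT replicate 1 account for the higher HSC-associated and lower neutrophil genes of bone marrow KO cells? Pair 2 does not contain it, and there the HSC-associated median of 0.55 lay at percentile 100 of matched random lists and the neutrophil median of -1.45 at percentile 0. Both directions therefore also appear in a pair without that array. Pair 2 cannot show how much that array adds to pair 1 or to the values over both pairs. These percentiles rest on 1 array per genotype and on random lists that do not keep genes of a cell type together. B lymphoid genes also lay at percentile 100 in pair 2, although their median was below 0 in pair 1 in both sources. A place at the extreme in pair 2 therefore does not settle the cause of the values in pair 1. The source of values for that array changes the HSC-associated median of pair 1 from 3.10 to 0.49 and hardly that of neutrophil genes (-2.40 and -2.32). Single neutrophil genes changed more and in opposite ways, with Mmp8 going from -8.30 to -4.72 and Elane from -2.32 to -4.67 in pair 1. The steady median therefore does not mean that the neutrophil values are free of that choice. A change of the KO cells themselves, the difference that the genotype groups name, stays open and was not tested. A different purity of the sorted cells, in each pair alike, could give the same values and was not tested.

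Whether the lower hepatocyte genes of fetal liver KO come from RNA of hepatocytes in the WT sample or from an effect of TIF1b within KSL cells was not tested. The sort for c-Kit positive, Sca-1 positive, lineage-negative cells should remove hepatocytes. The hepatocyte median was also below 0 in bone marrow in the value table, at -1.14 in pair 1 but 0.10 in pair 2.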

How the results depend on the processing

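Alternatives on the value table, the normexp correction on median signals, the random block and the table column among scanner files were chosen after the data were seen. The cause of a difference was not tested unless stated.

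With the value table in place of the scanner files the bone marrow count went from 0 to 113, the count over both tissues from 0 to 23, the tissue count from 287 to 3088, and the r between the tissues' KO effects from 0.0724 to 0.345. With the table column of the array labelled bone marrow WT replicate 1 among the scanner files these were 120, 23, 3083 and 0.345, which by construction places the difference in that array. The 3 sources of values were each fitted with and without the slide block, and all counts seen, before the table was given space. That rests on the mismatch of signals and on Kit, not on Trim28 or on the counts.

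Scaling moved a few counts. Quantile scaling gave 2 genes over both tissues in the scanner files, and 35 genes over both tissues and 89 interaction genes in the table. Normexp gave 433 genes at least 2-fold apart in fetal liver, against 1238, and 191 tissue genes. It also gave smaller differences for dim genes in bone marrow, at 5.22 against 8.07 for Cyp2b10, 3.66 against 7.42 for Ppp1r3g, 0.85 against 3.59 for Fbp2 and -1.45 against -4.42 for Tmem178. An intensity trend gave 43 genes over both tissues in the table.

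The filter on dim genes moved the fetal liver count from 1238 to 2006 without it and 574 with all arrays required. By construction the count there also follows the fold limit, with 525 genes at 4-fold and 2433 at 1.5-fold. In the table, no filter gave 11 bone marrow genes, against 113, 11 over both tissues, 1791 between tissues and r = 0.195. The filter on all arrays gave 27 bone marrow genes and r = 0.304.

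With replicate pairing or the slide as a block, which are the same fit, the table gave 982 bone marrow genes and 0 over both tissues. The random block gave 835 tissue genes in the table. Replicate 1 arrays alone gave 0 tissue genes in both sources. The bone marrow arrays alone gave 113 for the genotype effect of the table. Of the gene lists 0 passed with an estimated correlation and 0 with fry, in both sources.

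Leaving out 1 bone marrow array leaves the spread of the bone marrow and interaction fits to the 2 arrays of the other genotype. It moved the scanner counts from 0 to 2222 for bone marrow, 0 to 1 over both tissues, 1 to 1817 between tissues and 0 to 1390 for the interaction, and r from -0.0456 to 0.295, a reversed sign without bone marrow WT replicate 2. In the table the ranges were 335 to 651, 0 to 1, 1223 to 2199 and 154 to 273, and r from 0.298 to 0.333.

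Some alternatives fixed with the design could not be run. The files hold no mean signal for the planned normexp, each slide holds 1 tissue, so a fixed slide block or a within-slide fit of tissue cannot be made, and scan and slide are the same grouping. The lower signal of fetal liver and bone marrow replicate 1 leaves more genes near background there.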

Other observations

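The regroupings of arrays below were chosen after the results were seen. Replicate pair 2 of bone marrow is the brightest pair, and both of its arrays have nearly the same values in the scanner files and the table. In it, globin genes had a median KO minus WT difference of 2.62 over 5 genes and B lymphoid genes 1.26 over 21 genes. Immediate early genes had one of 0.43 and adult HSC-associated genes 0.32. All 4 lists lay at percentile 100 of matched random lists, from 1 array per genotype. Pair 1 did not repeat the immediate early and adult HSC-associated values, which were 0.0049 and -0.05 in the scanner files and -0.28 and -0.16 in the table, and neither list passed in limma's camera test. B lymphoid genes were lower in pair 1 in both sources.

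The 6 arrays can be divided into groups of 3 in 10 ways, too few for a share under 0.05. In the scanner files the real split had 0 genes, so it was fixed in advance that 10 of 10 splits had as many, and this count decides nothing. The highest other split had 1518. That split places the array labelled bone marrow WT replicate 1 with the fetal liver pair. As tissue is in the model, it sets this array against the other 3 bone marrow arrays, which points to a structure of the samples. The other splits that keep the fetal liver pair together likewise set 1 bone marrow array against 3. Over the table's values only the real split, 1 of 10, reached its 23 genes, and the highest other had 1. The splits were fitted without the slide, and with the slide as a block the real split gave 0 genes.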
